A study of Homo sapiens with 8 samples.

How the data were processed

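RNA was measured in K562 cells, a chronic myeloid leukaemia line with erythroid features, that carried dCas9-KRAB, a catalytically dead Cas9 fused to a repressor domain. The 8 libraries fall into 4 groups of 2: untransduced cells, cells with a control guide to the AAVS1 site (sgAAVS1), and cells with either of a pair of guides to IRF2 (sg1-IRF2 and sg2-IRF2). Per the labels, total RNA was taken with a column kit, in cells with a guide 7 days after transduction. It was treated with DNase and depleted of ribosomal RNA, and libraries were made with a directional kit. The submitters' processing notes name cutadapt, Bowtie2 and hg38. Their versions, the counting tool, the strand setting, the handling of duplicate reads and the annotation release are not given in the sources used here.

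The deposited values are log2 of reads per gene divided by 1 factor per library, with replicates kept apart. On the linear scale every value above the column minimum was a whole multiple of the value of 1 read (tolerance 0.01 read, 100% of the values in each library), and genes without reads were listed at the value of 0.9 read. The factor is therefore known only up to the library total behind it, which the values do not give. Whole reads were recovered from the values, and library sums over the listed genes ran from 5248359 to 6738348 reads. The recovered reads were used for depth, counting intervals, chi-square values between libraries, reads per exonic base, slopes of reads on library size and the simulated counts. They also entered the alternatives that fit reads or remove genes by reads per exonic base. The tests of genes and lists in the main fit used the deposited log2 values. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

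The table lists 35805 genes, 85 of them under a name that occurs more than once. Genes with a mean deposited log2 value at or above 0 over the 8 libraries were tested, 14665 in all, of which 12222 are protein coding. Of the tested genes 97.7% were matched to GENCODE release 29 by name and place, and 91.9% of those matched had the same span. Exons of 448 tested genes overlapped those of another gene on the same strand by at least 50%, which was not corrected for. Because the strand setting is not known, genes with another gene on the opposite strand are named as such.

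Group means were fitted to all 8 libraries in 1 linear model (limma 3.58.1 in R 4.3.3, lmFit, contrasts.fit and eBayes with a mean-variance trend). Residual degrees of freedom were 4 and prior degrees of freedom 22.4. The limma moderated test was two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and genes with adjusted p under 0.05 were called. Errors given with log2 differences are the standard errors of that model, and errors given with group values are the SD of 2 libraries. The comparisons were both IRF2 guides against sgAAVS1 (the mean of the guide means), each guide against sgAAVS1, sg1-IRF2 against sg2-IRF2, and sgAAVS1 against untransduced cells. All share 1 estimate of the spread. Both guides were also set against untransduced cells. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the plots.

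The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure the spread between libraries only. Between replicates, chi-square per degree of freedom of the recovered reads was 0.820 in untransduced cells, 1.66 with sgAAVS1, 0.780 with sg1-IRF2 and 0.659 with sg2-IRF2, where counting noise alone gives 1. A median chi-square below that of chance was also seen in 6 of the 24 pairs of libraries from different groups. These were the 4 pairs of an untransduced with an sg2-IRF2 library, and each sgAAVS1 library with the sg1-IRF2 library of its number (0.782 and 0.786 of chance, against 1.59 between the sgAAVS1 replicates). By the mean chi-square per gene, those 6 pairs lay above 1 (1.12 to 1.36). Replicate pairs lay below 1 in untransduced cells (0.806), with sg1-IRF2 (0.765) and with sg2-IRF2 (0.625). A low median thus also occurs between groups, but a mean below counting noise was seen only within groups. Real differences between groups raise the mean as well, so these values do not settle whether a pair is 1 library sequenced again. Both libraries of each group were kept as replicates. Replicate numbers were not used as pairs.

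Before the data were examined, 20 gene lists were fixed, with 4 members later found under an older symbol. They cover interferon-stimulated genes, antigen processing and MHC class I, other interferon regulatory factors, pyroptosis and caspases, nucleic acid sensing, interferon receptors and JAK-STAT, and NF-kB and inflammatory genes. Cell type lists cover erythroid, megakaryocyte, myeloid, lymphoid, and adherent epithelial and mesenchymal line genes. The rest are cell cycle and DNA replication, cell cycle inhibitors and apoptosis, integrated stress and unfolded protein response, histone genes, mitochondrially encoded genes, cytosolic ribosomal protein genes, the neighbours of IRF2 on 4q35 and the AAVS1 locus on 19q13. Each list was tested with camera at a preset correlation of 0.01 (adjusted over the 20 lists of a comparison), again with an estimated correlation, and with fry. Called members were counted with p adjusted over all genes tested and adjusted over the list alone.

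The rule for named genes was also fixed then. IRF2 came first. For both guides against sgAAVS1, the 12 highest and 12 lowest log2 differences were taken among called genes with a symbol other than a clone name, the same sign with each guide, and all 4 IRF2-guide libraries on 1 side of both sgAAVS1 libraries (64 higher and 136 lower genes passed). Every other comparison gave its 5 highest and 5 lowest called genes. Each list gave up to 4 called members by lowest p, with PPP1R12C always taken from its list. GSDMD, IRF1, ISG15, B2M and TAP1 were taken whether or not they were called. Genes named beyond that rule are said to have been chosen after their values were seen. The values of some genes, among them genes that the rule takes, are not reported here.

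The steps were tested on simulated data with 200 changed genes, 50 at each fold. For both guides against sgAAVS1 the test recovered 54% of genes changed 1.25-fold, 78% at 1.5-fold, 88% at 2-fold and 94% at 4-fold, and 5.11% of the calls were false. False calls made up 9.50% for 1 guide against sgAAVS1 (17 of 179), 4.68% between the guides (8 of 171) and 7.87% for sgAAVS1 against untransduced cells (14 of 178). Each comparison was simulated in 1 run, so differences between these shares can be chance. Simulated counts were drawn independently, spread at least as much as counting noise, and held no structure of the samples. The real replicates had a chi-square per degree of freedom from 0.659 (sg2-IRF2) to 1.66 (sgAAVS1), so these rates need not hold for them. The agreement of the guides was set against 100 simulations of unchanged groups that shared the sgAAVS1 libraries.

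Alternatives tried were no filter on low values and a stricter one (mean at or above 2), 1 unit added before the logarithm, quantile normalization, library medians aligned, a robust fit, a fit without the trend, array weights, replicate number as a block, only the groups compared, a 2-fold minimum, other controls, and leaving out each library in turn. Added after the data were seen were voom on the recovered reads, genes called against both control groups, removal of genes with at least 0.5 reads per exonic base, and list tests against untransduced cells.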

Results

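The series asks what loss of IRF2, a transcription factor that binds interferon-responsive promoters, does to the transcriptome of K562 cells. RNA from 8 libraries was analysed, 2 each from untransduced dCas9-KRAB cells, cells with the control guide sgAAVS1, cells with sg1-IRF2 and cells with sg2-IRF2. Recovered reads over the listed genes were 6303033 and 6320046 in untransduced cells, 5248359 and 6738348 with sgAAVS1, 5748809 and 6394922 with sg1-IRF2, and 6440681 and 6122710 with sg2-IRF2. The medians of the tested genes lay between 5.54 and 5.69 on the deposited log2 scale. Principal components were taken over the tested genes with a mean log2 value at or above 2. The first principal component, with 31.0% of the variance, placed untransduced and sg2-IRF2 libraries on 1 side and sgAAVS1 and sg1-IRF2 libraries on the other. The second component, with 24.7%, separated the 4 IRF2-guide libraries from the 4 control libraries.

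**Figure D1:**
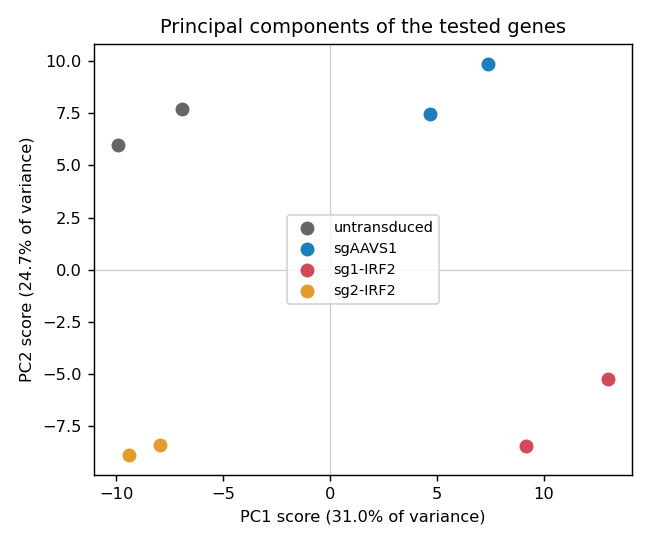
Scores of the 8 libraries on the first 2 principal components of the tested genes with a mean log2 value at or above 2 (horizontal axis 31.0% and vertical axis 24.7% of the variance), 1 point per library, coloured by group. IRF2-guide libraries have negative scores on the second component, and untransduced and sg2-IRF2 libraries have negative scores on the first.

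IRF2 itself, on the minus strand of chromosome 4 (184387713 to 184474580, hg38), fell with both guides. Its deposited log2 value was 5.59 ± 0.017 (SD, n = 2) in untransduced cells, 5.54 ± 0.13 with sgAAVS1, 0.14 ± 0.62 with sg1-IRF2 and 1.91 ± 0.0097 with sg2-IRF2. These values rest on 271 and 268 reads, 196 and 291 reads, 4 and 8 reads, and 22 and 21 reads. Against sgAAVS1 the mean of the guides was -4.51 ± 0.18 (SE), a 22.8-fold difference (limma moderated test, adjusted p = 2.5e-16). The fall was -5.39 ± 0.21 with sg1-IRF2 (adjusted p = 2.1e-16) and -3.62 ± 0.21 with sg2-IRF2 (adjusted p = 1.1e-12). IRF2 was thus lower with sg1-IRF2 than with sg2-IRF2, by -1.77 ± 0.21 (adjusted p = 9.7e-06), while sgAAVS1 and untransduced cells differed by -0.06 ± 0.21 (adjusted p = 0.93). None of the 11 tested neighbours of IRF2 on 4q35 was called in the main comparison, over all genes or adjusted over the list alone (1548 genes had an unadjusted p under 0.05, camera adjusted p = 0.703).

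**Figure D2:**
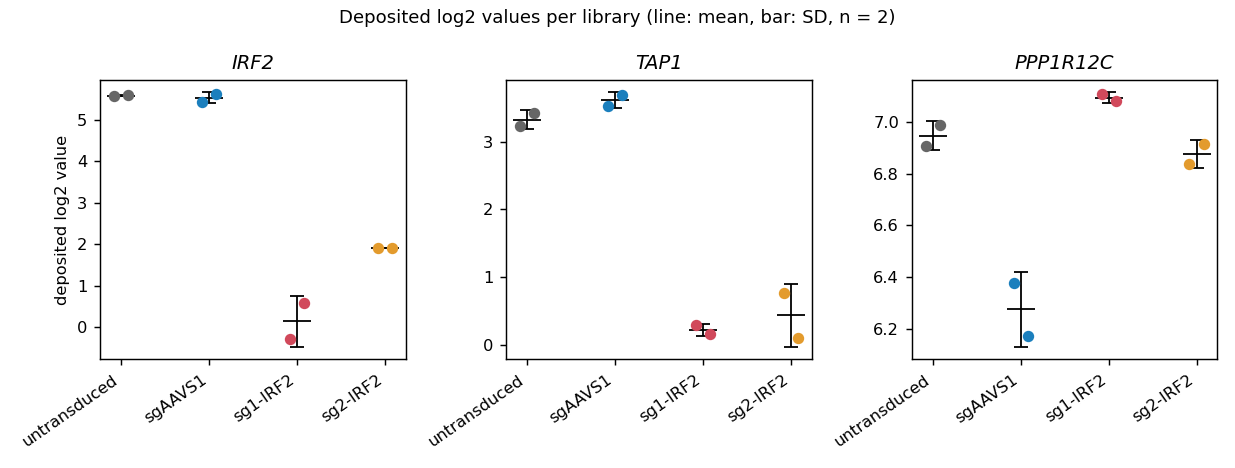
Deposited log2 values of IRF2, TAP1 and PPP1R12C in each library (points), with the mean (line) and SD (bar) of the 2 libraries per group. IRF2 and TAP1 are lower in the IRF2-guide libraries than in both control groups, and PPP1R12C is lower in the sgAAVS1 libraries than in the other 3 groups.

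In the main comparison, both IRF2 guides against sgAAVS1, genes of the interferon response and of antigen presentation fell. Besides IRF2, the lowest differences were in LGALS3BP, a secreted glycoprotein (-5.38 ± 0.40), APOL6, an apolipoprotein L family member (-3.85 ± 0.31), ERAP2, an aminopeptidase that trims peptides for MHC class I (-3.70 ± 0.28), and IFI6, an interferon-induced mitochondrial protein (-3.44 ± 0.38). TAP1, a subunit of the peptide transporter for MHC class I, fell by 3.28 ± 0.26, OAS3, an antiviral oligoadenylate synthetase, fell by 3.23 ± 0.25, and UBA7, the activating enzyme for ISG15, fell by 3.09 ± 0.26. DTX3L, a ubiquitin ligase partner of PARP9, fell by 3.06 ± 0.10, SAMD9, an antiviral factor, fell by 3.02 ± 0.21, C19orf66, an antiviral protein also known as shiftless, fell by 2.86 ± 0.16, and DHX58, an RNA sensor of the RIG-I family, fell by 2.67 ± 0.30. Adjusted p (limma moderated test, n = 2 per group) of these genes ran from 9.0e-18 for DTX3L to 8.3e-07 for DHX58. That all 4 IRF2-guide libraries lay below both sgAAVS1 libraries is part of the rule that named these genes. Each was also lower than in untransduced cells.

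Reads were few for some of these genes. LGALS3BP had 1 read over the sg1-IRF2 libraries against 145 with sgAAVS1, a ratio of 143 with a 95% counting interval of 25.3 to 5701. IFI6 had 3 reads against 64, a ratio of 21.1 (6.90 to 105). The fitted difference of LGALS3BP with sg1-IRF2 depends on the value given to genes without reads. DTX3L lies opposite PARP9, ERAP2 opposite CTD-2260A17.2 and C19orf66 opposite ANGPTL6, so their reads are not assigned with certainty. APOL6 (adjusted p = 0.0865) and DHX58 (adjusted p = 0.115) missed the threshold in a fit without the mean-variance trend.

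Of the 14665 genes tested, 233 were called in the main comparison, 72 higher and 161 lower. With a 2-fold minimum 48 were called, 10 higher and 38 lower. The share of higher genes among those called was 30.9%, and 40.9% with quantile normalization (99 higher, 143 lower). Without a library the count was 418 (sgAAVS1 replicate 1), 428 (sgAAVS1 replicate 2), 141 (sg1-IRF2 replicate 1), 151 (sg2-IRF2 replicate 1) and 141 (sg2-IRF2 replicate 2). Against all 4 control libraries as 1 group it was 117, with 9 higher and 108 lower.

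Interferon-stimulated genes fell as a list. Of 37 tested members, 14 were lower and 1 higher, and 20 were lower and 2 higher adjusted over the list alone (camera adjusted p = 5.0e-29, and adjusted p = 0.0082 with an estimated correlation). By lowest p these were DTX3L, PARP12 (-1.38 ± 0.07), a mono-ADP-ribosyltransferase, EIF2AK2 (-0.98 ± 0.05), the kinase PKR that halts translation on double-stranded RNA, and UBE2L6 (-2.39 ± 0.13), the conjugating enzyme for ISG15. EIF2AK2 lies opposite GPATCH11. The higher member, named after its value was seen, was SP100 (0.23), a nuclear body protein. ISG15, the ubiquitin-like modifier, had -0.33 ± 0.15 (adjusted p = 0.44).

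Genes of antigen processing and MHC class I fell too. Of 14 tested members, 8 were lower and 0 higher, and 10 were lower adjusted over the list alone (camera adjusted p = 2.8e-28, and adjusted p = 0.0158 with an estimated correlation). TAP2, the other subunit of the peptide transporter, fell by 2.19 ± 0.09, and ERAP1, the aminopeptidase paired with ERAP2, fell by 1.43 ± 0.07. ERAP1 lies opposite CAST. The other called members, named after their values were seen, were HLA-C (-2.38), the proteasome genes PSME1 (-1.10) and PSMB10 (-0.59), and the peptide-loading factor TAPBP (-0.41). HLA genes are similar in sequence, so reads of HLA-C are not assigned with certainty. B2M, the light chain of MHC class I, had 0.03 ± 0.06 (adjusted p = 0.90) and 641 and 652 reads in untransduced cells.

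Nucleic acid sensing genes gave 2 lower of 10 tested members, DHX58 and SAMHD1, and 3 lower adjusted over the list alone (camera adjusted p = 2.3e-04). SAMHD1, a nucleotide hydrolase that restricts retroviruses, fell by 0.34 ± 0.07 (adjusted p = 0.0048), but missed the threshold against untransduced cells (-0.20, adjusted p = 0.14) and without the trend (adjusted p = 0.195). The call of the list was lost with an estimated correlation (adjusted p = 0.181 with an estimated correlation) and against untransduced cells (adjusted p = 0.566). Among pyroptosis and caspase genes 1 of 14 was called, GSDMD, the pore-forming effector of pyroptosis (-0.81 ± 0.19, adjusted p = 0.023), with 1 lower and 1 higher adjusted over the list alone and a list adjusted p of 0.553. GSDMD missed the threshold with quantile normalization (-0.76, adjusted p = 0.054), without the trend (0.340), with array weights (0.0848) and with only the groups compared (0.0622). It also missed it without untransduced replicate 1 or 2 (0.053 and 0.0573), sgAAVS1 replicate 1 or 2 (0.0535 and 0.0512), sg1-IRF2 replicate 2 (0.0724) or sg2-IRF2 replicate 1 (0.104). Against untransduced cells GSDMD differed by -0.91 ± 0.19 (adjusted p = 0.0058).

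IRF1, the related activator of the same promoters, had -0.09 ± 0.09 (adjusted p = 0.79), and 0 of 8 tested interferon regulatory factor genes other than IRF2 were called by limma, over all genes or adjusted over the list alone (list adjusted p = 0.543). Of 16 genes of interferon receptors and JAK-STAT 1 was higher, also adjusted over the list alone, SOCS1, a feedback inhibitor of JAK-STAT signalling (0.43 ± 0.09, adjusted p = 0.0074, list adjusted p = 0.465). SOCS1 lies opposite RMI2, and it differed from untransduced cells by 0.19 ± 0.09 (adjusted p = 0.35). Its call was lost without sgAAVS1 replicate 1 (0.30, adjusted p = 0.120) and without the trend (adjusted p = 0.195). Of 19 cell cycle inhibitor and apoptosis genes 1 was lower, the inhibitor CDKN1A (-0.28 ± 0.07, adjusted p = 0.033), with 3 lower and 2 higher adjusted over the list alone (list adjusted p = 0.703). COL1A1, a fibrillar collagen, was the 1 called gene of 8 on the adherent line list (-0.32 ± 0.08, adjusted p = 0.033, and 0.051 with library medians aligned), with 2 lower adjusted over the list alone (list adjusted p = 0.465).

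The calls of CDKN1A and COL1A1 depended on single libraries. CDKN1A missed the threshold without untransduced replicate 1 or 2 (adjusted p = 0.0559 and 0.0563), sgAAVS1 replicate 2 (0.104), sg1-IRF2 replicate 1 or 2 (0.106 and 0.0622) and sg2-IRF2 replicate 1 or 2 (0.118 and 0.112). It also missed it without the trend (0.0968), with array weights (0.112) and with only the groups compared (0.0638), and against untransduced cells it was lower by -0.59 ± 0.07 (adjusted p = 1.7e-06). COL1A1 missed the threshold without untransduced replicate 1 or 2 (0.0697 each), sgAAVS1 replicate 2 (0.248), sg1-IRF2 replicate 1 (0.158) and sg2-IRF2 replicate 1 or 2 (0.0593 and 0.143). For COL1A1 the adjusted p was 0.324 without the trend, 0.0913 with array weights, 0.052 with voom, 0.071 with only the groups compared and 0.0505 against untransduced cells.

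Cell cycle and DNA replication genes gave no called member of 32 by limma, also adjusted over the list alone, and a camera adjusted p of 0.0182 downwards. That call was lost with an estimated correlation (adjusted p = 0.986 with an estimated correlation) and with library medians aligned (adjusted p = 0.0932), and the direction turned against untransduced cells (adjusted p = 0.0105, and adjusted p = 0.855 with an estimated correlation). Without sgAAVS1 replicate 1 the direction also turned (adjusted p = 0.515), and without sg1-IRF2 replicate 2 or sg2-IRF2 replicate 1 the call was lost (adjusted p = 0.257 and 0.168). No member was called by limma, over all genes or adjusted over the list alone, among 29 erythroid genes (list adjusted p = 0.335), 52 histone genes (0.335), 19 integrated stress and unfolded protein response genes (0.714), 11 myeloid genes (0.663), 14 NF-kB and inflammatory genes (0.465), 81 cytosolic ribosomal protein genes (0.880), 13 mitochondrially encoded genes (0.986) and 3 lymphoid genes (0.880). Of 10 megakaryocyte genes none was called over all genes and 1 was higher adjusted over the list alone (list adjusted p = 0.997). The camera values here use the preset correlation of 0.01. Estimated correlations were 0.792 for ribosomal protein, 0.917 for mitochondrially encoded, 0.474 for histone, 0.387 for integrated stress and 0.212 for erythroid genes. Used in camera over all libraries, they gave these lists adjusted p from 0.986 to 0.999. In a fit without 1 sgAAVS1 replicate the other replicate is the whole control, and the main difference is the mean of both such fits. A list called in both of them but not in the main comparison is therefore not repeated evidence of 1 shift. The directions in these fits are not given here. Leaving out 1 library brought some of these lists past the threshold. Without sgAAVS1 replicate 1 these were ribosomal protein (1.5e-14), mitochondrially encoded (2.2e-07), histone (1.0e-05) and integrated stress genes (7.7e-04). Without sgAAVS1 replicate 2 they were ribosomal protein (1.4e-16), mitochondrially encoded (3.2e-07), integrated stress (0.0207) and erythroid genes (0.00424), and without sg1-IRF2 replicate 2 histone genes (0.0323).

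**Figure D3:**
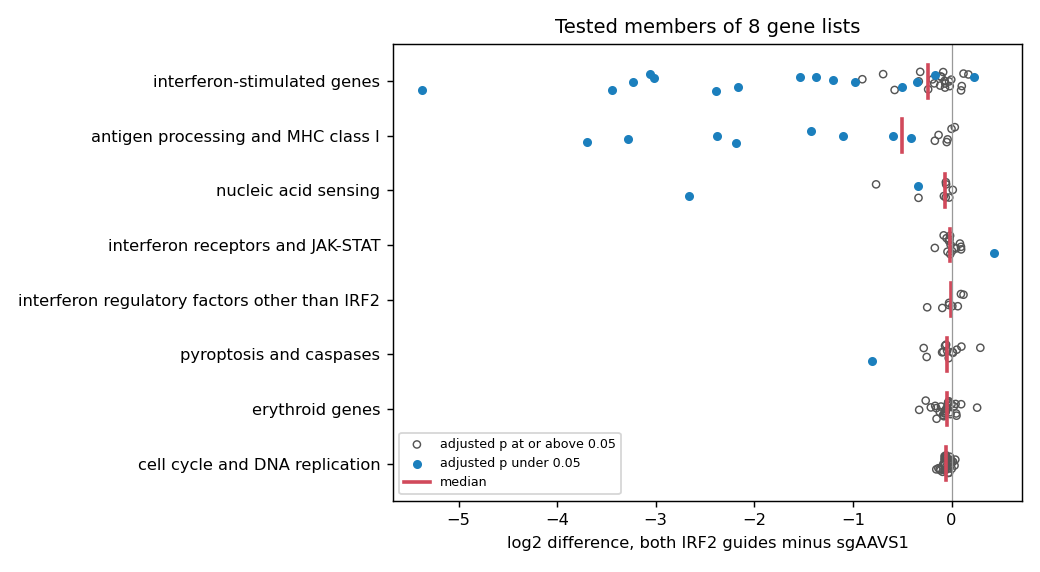
Log2 differences, both IRF2 guides minus sgAAVS1, of the tested members of 8 gene lists, 1 point per gene, filled where adjusted p is under 0.05, with the median of each list as a line. Called members lie below 0 in the interferon-stimulated list except SP100, and all 8 called members of the antigen processing list lie below 0.

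Higher genes of the main comparison were mostly genes that were low in the sgAAVS1 libraries alone. THBD, the thrombin receptor thrombomodulin, had 0 reads with sgAAVS1, 36 and 45 reads in untransduced cells, 25 and 34 with sg1-IRF2, and 28 and 23 with sg2-IRF2. Against a floor of 3 reads over the sgAAVS1 group this is at least 19.9-fold higher with sg1-IRF2, at least 15.4-fold higher with sg2-IRF2 and at least 25.1-fold higher in untransduced cells. ZNF660, a zinc finger gene, had 1 read with sgAAVS1, with ratios of 27.3 (95% counting interval 4.50 to 1118) for sg1-IRF2, 19.1 (3.07 to 789) for sg2-IRF2 and 16.8 (2.65 to 698) for untransduced cells. SNCG, which encodes gamma-synuclein, was higher by 2.52 ± 0.10, and MMRN2, an endothelial matrix protein gene, by 2.85 ± 0.46. SNCG and MMRN2 overlap on opposite strands. RAB11FIP5, a Rab11 effector, was higher by 2.19 ± 0.08, and DBNDD2 by 1.48 ± 0.08, with the readthrough gene SYS1-DBNDD2, which shares exons with it, at 1.32 ± 0.08. The remaining named genes were PNCK, a calcium/calmodulin-dependent kinase (1.12 ± 0.06), C10orf10, an autophagy regulator also known as DEPP1 (0.81 ± 0.20), SNX33, a sorting nexin (0.73 ± 0.05), PLD2, a phospholipase (0.71 ± 0.14), and PPP1R12C, a myosin phosphatase subunit whose gene holds the AAVS1 site (0.71 ± 0.05). PNCK lies opposite SLC6A8 and SNX33 opposite IMP3. Adjusted p ran from 1.0e-17 for RAB11FIP5 to 0.027 for C10orf10. C10orf10 missed the threshold without untransduced replicate 1 or 2 (0.0565 and 0.0542), sgAAVS1 replicate 2 (0.113), sg1-IRF2 replicate 1 (0.0708) or sg2-IRF2 replicate 1 (0.111), without the trend (0.0631), with array weights (0.104), with voom (0.106) and with only the groups compared (0.0695). MMRN2 (0.196) and PLD2 (0.121) missed it without the trend.

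Against untransduced cells none of these 12 genes was called. PPP1R12C differed by 0.04 ± 0.05 (adjusted p = 0.85), SNCG by 0.13 ± 0.10 (adjusted p = 0.64), RAB11FIP5 by 0.03 ± 0.08 (adjusted p = 0.93) and PNCK by -0.22 ± 0.06 (adjusted p = 0.070). The AAVS1 locus list had 1 higher gene of 15, PPP1R12C, also adjusted over the list alone (camera adjusted p = 0.0182, and adjusted p = 0.523 with an estimated correlation). Its call was lost without sgAAVS1 replicate 2 (adjusted p = 0.124) and against untransduced cells (adjusted p = 0.787).

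Of the 161 lower genes 83, among them IRF2, TAP1 and LGALS3BP, were also lower than in untransduced cells. The median of the 161 genes was -0.43 against sgAAVS1 and -0.30 against untransduced cells. Of the 72 higher genes 7 were also higher than in untransduced cells, 7 were lower and 58 were not called. Independent lists of these sizes would share 2.44 lower and 0.707 higher genes, which leaves out the IRF2-guide libraries that both comparisons use. In 100 simulations of unchanged groups no gene was called alike, but these call few genes at all, so neither number shows how much of the overlap is a shared effect. The covariance of the differences across genes was 0.0271, against a simulated mean of 0.0101. Of those 72 genes 54 were called lower in sgAAVS1 than in untransduced cells (1.29 by independence, 0 in the simulations), and part of that overlap can come from the sgAAVS1 libraries that both comparisons use. Across all genes those differences had a correlation of -0.530 (simulated mean -0.579) and a covariance of -0.0349 (simulated mean -0.0205). The median of the 72 genes was 0.34 against sgAAVS1 and -0.01 against untransduced cells, and neither depends on the value given to THBD. With the 2-fold minimum, 36 of the 38 lower genes and 0 of the 10 higher genes were called in the same direction against untransduced cells. The 7 genes higher than in both control groups, named after their values were seen, were SP100, ADAMTS6, FAM208B, ZNF136, ZNF850, RBCK1 and CXorf38, with differences against sgAAVS1 of 0.23 to 0.58.

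**Figure D4:**
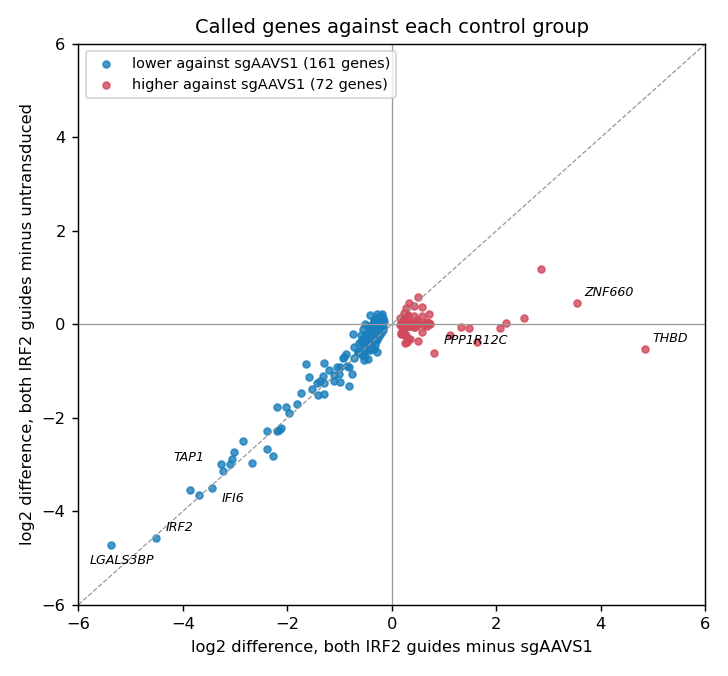
Log2 differences of the 233 called genes, both IRF2 guides minus sgAAVS1 (horizontal axis) and both guides minus untransduced cells (vertical axis), 1 point per gene, with the line of equal differences dashed. Genes lower against sgAAVS1 by several log2 units lie near the dashed line, and most genes higher against sgAAVS1 lie near 0 on the vertical axis; points of THBD, ZNF660 and LGALS3BP depend on the value given to genes without reads.

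With sg1-IRF2 alone against sgAAVS1, the lowest genes were LGALS3BP, IRF2, IFI6, ERAP2 (-3.90 ± 0.32) and MT1G (-3.75 ± 0.48), a metallothionein that binds zinc and copper. MT1G had 30 and 33 reads with sgAAVS1 and 0 and 6 reads with sg1-IRF2, and metallothionein genes are close copies of each other, so its reads are not assigned with certainty. THBD, ZNF660, MMRN2, SNCG (2.54 ± 0.12) and RAB11FIP5 (2.16 ± 0.09) were the highest. Of 37 interferon-stimulated genes 13 were lower and 2 higher (15 and 4 adjusted over the list alone), and 7 of 14 antigen processing genes were lower (8 adjusted over the list alone). MT1G (0.296) and MMRN2 (0.246) missed the threshold without the trend. Both lists kept the call with an estimated correlation (adjusted p = 0.00453 and adjusted p = 0.00806 with an estimated correlation). Called genes numbered 121, 48 higher and 73 lower. The share of higher genes was 39.7%, and 29.3% with library medians aligned (34 higher, 82 lower). The count was 237 without sgAAVS1 replicate 1, 236 without sgAAVS1 replicate 2 and 76 without sg1-IRF2 replicate 1.

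With sg2-IRF2 alone against sgAAVS1, LGALS3BP (-4.52 ± 0.46), APOL6 (-4.49 ± 0.36), IRF2, ERAP2 (-3.49 ± 0.32) and TAP1 (-3.17 ± 0.30) were the lowest, and THBD, ZNF660, SNCG (2.51 ± 0.12), MMRN2 (2.44 ± 0.53) and RAB11FIP5 (2.22 ± 0.09) the highest. MMRN2 missed the threshold without sg2-IRF2 replicate 2 (adjusted p = 0.0646), without the trend (0.155) and with only the groups compared (0.0607), and APOL6 without the trend (0.0714). Of 37 interferon-stimulated genes 19 were lower and 0 higher, also adjusted over the list alone, and 8 of 14 antigen processing genes were lower (9 adjusted over the list alone). With an estimated correlation the first list kept its call (adjusted p = 0.0280 with an estimated correlation) and the second did not (adjusted p = 0.0543 with an estimated correlation). Called genes numbered 1196, 154 higher and 1042 lower. The share of higher genes was 12.9%, but 52.6% with library medians aligned (263 higher, 237 lower) and 51.5% with quantile normalization (319 higher, 300 lower). The count was 1923 without sgAAVS1 replicate 2, 384 without sg2-IRF2 replicate 1 and 227 without sg2-IRF2 replicate 2.

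The guides shared 59 genes lower and 33 genes higher than sgAAVS1, where independent lists would share 5.19 and 0.504. Simulated unchanged groups with a shared control shared none, but called at most 2 genes in 1 direction, so part of the excess can come from the shared sgAAVS1 libraries. Of the 83 genes lower than in both control groups, 55 were called lower with each guide alone, among them IRF2, TAP1, DTX3L and OAS3. Across genes, which are not independent replicates, the differences of sg1-IRF2 and sg2-IRF2 against the same sgAAVS1 libraries had a Pearson correlation of 0.596 and a Spearman correlation of 0.421. Unchanged groups that shared the control gave means of 0.501 and 0.447. With disjoint controls the Pearson correlation was 0.278 (sg1-IRF2 against sgAAVS1, sg2-IRF2 against untransduced cells) and 0.0395 (the controls exchanged), and the Spearman correlation was 0.103 and -0.267. The covariance was 0.0463, against a simulated mean of 0.0205. The simulations hold only the spread between libraries, so a real departure of the sgAAVS1 group could add to the shared part. With disjoint controls the covariance was 0.0193 (sg1-IRF2 against sgAAVS1, sg2-IRF2 against untransduced cells) and 0.0034 (the controls exchanged).

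Between the guides, the median of all genes was higher in sg1-IRF2 than in sg2-IRF2 by 0.11 on the log2 scale. Relative to that shift, IRF2 was lower with sg1-IRF2 by -1.88 (adjusted p = 1.0e-04), and IFI6, with 3 reads against 13, by -2.15 (adjusted p = 0.015). On the deposited scale the lowest genes were LAMC1, a laminin chain, with 3 reads against 28 (ratio of sg2-IRF2 to sg1-IRF2 8.38, 95% counting interval 2.59 to 43.1), MT1G (-2.94 ± 0.48), MT1E, another metallothionein, with 2 reads against 16 (ratio 7.19, 1.69 to 64.4), IFI6 and IRF2. An sg1-IRF2 library held no MT1G reads, so the size of its difference depends on the value given to genes without reads. The highest were FRK, a tyrosine kinase (1.75 ± 0.49), MDGA1, a cell surface glycoprotein (1.72 ± 0.54), the overlapping genes SLX1A-SULT1A3 and SLX1A (1.54 ± 0.43 and 1.54 ± 0.44), which have a second copy in the genome, and SPOCK2, a proteoglycan (1.53 ± 0.44). With library medians aligned none of these 5 higher genes was called by limma, with adjusted p from 0.108 for FRK to 0.190 for MDGA1. Nor was any of them called with no filter on low values (adjusted p from 0.107 to 0.176), quantile normalization (0.0883 to 0.173) or voom (0.0821 to 0.177).

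Several of these calls depended on 1 library. MT1E missed the threshold without sg1-IRF2 replicate 2 (adjusted p = 0.0997) and sg2-IRF2 replicate 1 (0.058), and IFI6 without sg1-IRF2 replicate 2 (0.0939) and sg2-IRF2 replicate 2 (0.0662). FRK, MDGA1, SLX1A-SULT1A3, SLX1A and SPOCK2 each missed it without sg1-IRF2 replicate 1 (adjusted p from 0.109 to 0.177), sg1-IRF2 replicate 2 (0.116 to 0.138) and sg2-IRF2 replicate 2 (0.0862 to 0.549), where MDGA1 fell to 0.53. Without sg2-IRF2 replicate 1 FRK (0.142), SLX1A (0.0666) and SPOCK2 (0.0833) missed it, and MDGA1 without untransduced replicate 1 or 2 (0.0624 and 0.0635). LAMC1 (0.111), MT1G (0.141), MT1E (0.115) and IFI6 (0.116) missed it without the trend, as did the 5 higher genes (0.117 to 0.227), and IFI6 had -0.73 with 1 unit added (0.0507), -1.80 with voom (0.0673) and an adjusted p of 0.0544 with only the groups compared.

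Of 19 integrated stress and unfolded protein response genes 10 were higher with sg1-IRF2 than with sg2-IRF2 (11 adjusted over the list alone, camera adjusted p = 6.1e-04, and adjusted p = 0.723 with an estimated correlation). With library medians aligned 5 were higher and 1 lower. The called members, named after their values were seen, included CHAC1 (1.16), a glutathione-degrading enzyme, ATF5 (0.56), a stress transcription factor, and the serine synthesis enzymes PSAT1 (0.50) and PHGDH (0.44). ATF5 (0.34, adjusted p = 0.0018) and PSAT1 (0.27, adjusted p = 0.0048) were also higher in sgAAVS1 than in untransduced cells with medians aligned. Cell cycle and DNA replication genes had 16 higher of 32 (21 adjusted over the list alone, camera adjusted p = 4.7e-05, and adjusted p = 0.723 with an estimated correlation), but 1 higher with library medians aligned. Of interferon-stimulated genes 3 were higher and 5 lower (7 and 7 adjusted over the list alone, camera adjusted p = 0.0241 downwards, and adjusted p = 0.723 with an estimated correlation); the list's median was 0.12 and its mean -0.09. With library medians aligned 0 of them were higher and 5 lower (camera adjusted p = 0.106), and with quantile normalization 0 and 6. In all 1952 genes were called, 1859 higher in sg1-IRF2 and 93 lower. The share of higher genes was 95.2%, but 37.2% with library medians aligned (86 higher, 145 lower) and 38.3% with quantile normalization (110 higher, 177 lower). The count was 3605 and 3628 without sgAAVS1 replicates 1 and 2, 890 and 115 without sg1-IRF2 replicates 1 and 2, and 373 and 194 without sg2-IRF2 replicates 1 and 2.

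The control guide was compared with untransduced cells as background for the IRF2 guides. PPP1R12C fell with sgAAVS1 by 0.67 ± 0.06 (adjusted p = 7.5e-08), the 1 called gene of 15 on the AAVS1 locus list (2 lower adjusted over the list alone, list adjusted p = 0.143). THBD, ZNF660, SNCG (-2.39 ± 0.12), DLGAP4-AS1 (-2.18 ± 0.63, opposite DLGAP4 and MYL9) and RAB11FIP5 (-2.16 ± 0.09) were the lowest. The highest had few reads: PTAFR, the receptor for platelet-activating factor (2.51 ± 0.63), BAAT, a bile acid conjugating enzyme (2.01 ± 0.58), MIR503HG, a microRNA host gene (1.71 ± 0.51), KCTD12 (1.63 ± 0.40) and FAM186B (1.38 ± 0.38, opposite PRPF40B). Some sizes depended on 1 library. DLGAP4-AS1 was -0.89 without sgAAVS1 replicate 1, and -2.82 and -1.54 without untransduced replicates 1 and 2. PTAFR and BAAT were 1.19 each without untransduced replicate 1, and 2.09 and 2.04 without sgAAVS1 replicate 1. With library medians aligned DLGAP4-AS1, BAAT and MIR503HG missed the threshold (adjusted p = 0.064, 0.064 and 0.058), as with quantile normalization (0.059, 0.054 and 0.055). With no filter on low values DLGAP4-AS1 (0.115), BAAT (0.184), MIR503HG (0.318), KCTD12 (0.067) and FAM186B (0.188) missed it. With array weights DLGAP4-AS1 (0.076), BAAT (0.12), MIR503HG (0.1365) and FAM186B (0.097) did. With 1 unit added DLGAP4-AS1 (0.063) and MIR503HG (0.066) missed the threshold. So did MIR503HG and FAM186B with voom (0.051 each), and MIR503HG with only the groups compared (0.096). With a replicate block BAAT (adjusted p = 0.0758) and MIR503HG (0.0656) missed it. Without the trend PTAFR, BAAT, MIR503HG, KCTD12, FAM186B, DLGAP4-AS1 and ZNF660 missed it, with adjusted p from 0.0898 for ZNF660 to 0.328 for DLGAP4-AS1. Without untransduced replicate 1 the threshold was missed by PTAFR (0.355), BAAT (0.436), MIR503HG (0.25), FAM186B (0.191) and DLGAP4-AS1 (0.108), and without untransduced replicate 2 by KCTD12 (0.198), MIR503HG (0.105), FAM186B (0.0956), DLGAP4-AS1 (0.39) and ZNF660 (0.0584). Without sgAAVS1 replicate 1 it was missed by PTAFR (0.0832), BAAT (0.0763), MIR503HG (0.197), FAM186B (0.185) and DLGAP4-AS1 (0.413), and without sgAAVS1 replicate 2 by BAAT (0.0645) and KCTD12 (0.0859). Leaving out an IRF2-guide library, which changes the shared spread alone, also ended the calls of BAAT, MIR503HG and DLGAP4-AS1 (adjusted p from 0.0508 to 0.0627).

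Erythroid genes gave 4 higher of 29 with sgAAVS1 (7 adjusted over the list alone, camera adjusted p = 0.00520, and adjusted p = 0.787 with an estimated correlation). Named after their values were seen, these included the embryonic and minor globin genes HBZ (0.38) and HBM (0.88) and the haem synthesis enzyme ALAS2 (0.31). Of 32 cell cycle genes 3 were higher, also adjusted over the list alone (camera adjusted p = 1.8e-04, and adjusted p = 0.787 with an estimated correlation), and histone genes had a camera adjusted p of 0.00101 upwards with 0 of 52 called by limma (2791 genes had an unadjusted p under 0.05, and adjusted p = 0.787 with an estimated correlation). Of 37 interferon-stimulated genes 1 was lower, also adjusted over the list alone (list adjusted p = 0.615), and of 14 antigen processing genes 1 was higher, TAP2 (0.42 ± 0.11, adjusted p = 0.019). Called genes numbered 697, 435 higher and 262 lower. The share of higher genes was 62.4%, and 46.6% with library medians aligned (302 higher, 346 lower). The count was 183 and 262 without untransduced replicates 1 and 2, and 1456 without sgAAVS1 replicate 2.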

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

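Of the tests in this part, those of library scaling and of a response beyond scaling for the imbalance between the guides were chosen only after the result was seen. Library scaling for the stress genes, GC content and the splits of the libraries were set up before their results were seen.

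A difference between the IRF2 guides themselves, by the limma moderated test of sg1-IRF2 against sg2-IRF2, brought these results here. Lower with sg1-IRF2 were LGALS3BP (-1.71), IRF2 (-1.77), IFI6 (-2.04), OAS3 (-1.03), UBA7 (-0.93), DTX3L (-0.71), C19orf66 (-0.82), PNCK (-0.32), TAP2 (-0.34) and UBE2L6 (-0.74). Higher were APOL6 (1.28), PPP1R12C (0.22) and SAMHD1 (0.34). With library medians aligned IRF2, IFI6, OAS3, DTX3L, C19orf66, PNCK, TAP2 and UBE2L6 stayed past the threshold, while LGALS3BP (adjusted p = 0.0564), APOL6 (0.169), UBA7 (0.0964), PPP1R12C (0.492) and SAMHD1 (0.134) did not. LGALS3BP and IFI6 had 1 and 3 reads with sg1-IRF2.

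Lists that differed between the guides were antigen processing (camera adjusted p = 0.0153), cell cycle (4.7e-05), histone (0.0296), integrated stress (6.1e-04), interferon-stimulated (0.0241) and mitochondrially encoded genes (0.0153). None of the 6 was called with an estimated correlation, where the smallest adjusted p was 0.723. With medians aligned the values were 0.00905, 0.0298, 0.0133, 0.00905, 0.106 and 0.109, in the same order.

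The count of 1952 genes between the guides was 95.2% higher in sg1-IRF2. GC content is argued against as the cause, since the medians of the highest and the lowest GC quintile of genes differed by only 0.013, against a shift of 0.11 over all genes. With library medians aligned 37.2% of the called genes were higher in sg1-IRF2 and 1.58% of the genes tested were still called. The imbalance went with the scale of the libraries. On the linear scale the deposited values summed to 1.170e+06 and 1.193e+06 with sg1-IRF2, against 1.096e+06 and 1.102e+06 with sg2-IRF2. The sums and the share of 37.2% argue against changes of separate genes as the source of the 95.2%. Library scaling and a true shift of all genes cannot be told apart, since centring would remove both and the library totals are not known. Medians of replicates differed by at most 0.057. Without sg1-IRF2 replicate 2 the count was 115, and it was 890 and 373 without sg1-IRF2 replicate 1 and sg2-IRF2 replicate 1, 194 without sg2-IRF2 replicate 2, and 3605 and 3628 without sgAAVS1 replicates 1 and 2.

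Integrated stress genes kept a median difference of 0.09 (0.0925) between the guides with library medians aligned, and an adjusted p of 0.00905, but 0.884 with an estimated correlation. Scaling cannot be told apart from a change of these genes, because the median lay between the bounds set for either.

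For 4 IRF2-guide against 4 control libraries, 84 genes were called, and 2 of the 35 splits of the 8 libraries gave as many, the real one included, so chance is not excluded by that count. The highest other split, untransduced and sg2-IRF2 against sgAAVS1 and sg1-IRF2, called 2285 genes, and the other 33 called none. That points to a structure of the samples: with medians aligned that split still called 1082 genes, 518 of them higher in sgAAVS1 and sg1-IRF2, and the real one 92.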

How the results depend on the processing

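Chosen only after the results were seen were voom on the recovered reads, calls against both control groups and list tests against untransduced cells. IRF2 kept its direction and call under every alternative run, from -4.73 to -3.90, and the lists of interferon-stimulated and antigen processing genes kept theirs, with adjusted p of at most 0.0082 and 0.0158 (0.0105 and 0.0229 with both untransduced cells as the control and an estimated correlation). In the fits that left out 1 library, the lone library of a group was assumed to vary like the other groups. Other filters, a 2-fold minimum and fewer libraries change counts by construction; the cause of the other changes was not tested. With a replicate block the counts were 201, 113, 1111, 1798 and 641, in the order below; across 12500 genes, deviations from the group mean correlated between groups at -0.0794 to 0.216, highest for sgAAVS1 with sg1-IRF2.

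For both guides against sgAAVS1 (233 genes), the count was 636 with no filter, 60 without the trend, 137 with array weights, 48 at a 2-fold minimum, 366 against untransduced cells, 117 against all 4 controls as 1 group, 92 with each guide, 90 against both control groups, and 141 to 428 without 1 library. For sg1-IRF2 (121), it was 359 with no filter, 45 without the trend, 48 at 2-fold and 76 to 237 without 1 library. For sg2-IRF2 (1196), it was 619 with quantile normalization, 500 with medians aligned, 57 without the trend, 562 with voom, 534 with only the groups compared, 72 at 2-fold and 227 to 1923 without 1 library. Between the guides (1952), it was 287 with quantile normalization, 231 with medians aligned, 2 without the trend, 4011 with array weights, 230 with voom, 4033 with only the groups compared, 50 at 2-fold and 115 to 3628 without 1 library. For sgAAVS1 against untransduced cells (697), it was 1184 with no filter, 11 without the trend, 397 with array weights, 25 at 2-fold and 183 to 1456 without 1 library.

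The correlation of the guides (0.596) was 0.548 with no filter, 0.623 with the stricter filter, 0.278 and 0.0395 with disjoint controls, and 0.518 to 0.714 without 1 library. Adjusted p of the AAVS1 locus list was 0.523 with an estimated correlation, 0.787 against untransduced cells, 0.543 with fry and a replicate block, and 0.0028 to 0.124 without 1 library. For cell cycle genes it was 0.986, 0.0932 with medians aligned, 0.0105 upwards against untransduced cells, 0.736 with fry and a replicate block, and 5.6e-08 to 0.515 without 1 library. For nucleic acid sensing it was 0.181, 0.566 and 0.0602 with fry and a replicate block. Against untransduced cells erythroid genes had 0.0194 and histone genes 4.5e-09, but 0.855 each with an estimated correlation. Without 1 library the range was 1.4e-16 to 0.889 for ribosomal protein genes, 0.00424 to 0.626 for erythroid genes, 1.0e-05 to 0.856 for histone genes, 7.7e-04 to 0.974 for integrated stress genes and 2.2e-07 to 0.944 for mitochondrially encoded genes.

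Of the single-gene values, 1318 kept their direction and side of the threshold, 172 lost and 4 gained the threshold, and 5 reversed, all against untransduced cells: THBD (-0.52), DBNDD2 (-0.069), SYS1-DBNDD2 (-0.054), PNCK (-0.22) and C10orf10 (-0.61). The search for IRF motifs in promoters was not run, because a genome sequence was not used here. At 5248359 to 6738348 reads per library, genes with a few reads per group carry wide counting intervals.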

Other observations

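The tests below of the higher genes against sgAAVS1 and against loss of IRF2, of the read ceiling, and of chromosome 19 zinc finger genes were chosen only after the results were seen, while that of read density was set up before. A test of repression spreading from the sgAAVS1 site, set up beforehand with the wrong direction, is not used. The comparison of hypoxia-induced genes in sg1-IRF2 with each control group was added after the guides had been compared.

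The genes of this paragraph were named after their values were seen, and the paragraph holds no test of them as a group. Lower in the main comparison were PARP9 (-2.16) and PARP14 (-1.20), members of the tested interferon-stimulated list, PARP10 (-1.30), and the apolipoprotein L gene APOL1 (-1.75), while APOL2 had -0.36 (adjusted p = 0.059). Butyrophilins BTN3A1 (-1.29) and BTN3A2 (-1.59), which take part in activating gamma-delta T cells, fell, and BTN3A3 had 0.24 (adjusted p = 0.65). IL17RC (-1.11), a subunit of the interleukin 17 receptor, TRIM34 (-1.82) and TRIM56 (-0.37) also fell. Members of such gene families are similar in sequence, so single members are not assigned with certainty. PARP9 lies opposite DTX3L.

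Metallothionein genes MT1X and MT2A, chosen after their values were seen, were lower with sg1-IRF2 than with sg2-IRF2 by -1.80 and -0.86 with library medians aligned. Genes higher with sg1-IRF2 included the amino acid transporters SLC7A5 (0.32) and SLC6A9 (0.77). MT1X (-0.53, adjusted p = 0.029), SLC7A5 (0.32, adjusted p = 3.4e-04) and SLC6A9 (0.38, adjusted p = 0.020) also differed in the same direction in sgAAVS1 against untransduced cells. For these the direction is therefore not particular to the guides, but for MT1X and SLC6A9 the difference between the guides was the larger. With both guides, MT1X was called lower than sgAAVS1 (-0.81) and than untransduced cells (-1.32). MT2A, MT1E and MT1G were likewise called lower than each control group. Among genes lower with sg1-IRF2, some are known targets of hypoxia-inducible factors, and a list of such genes was written after NDRG1, HK2, GBE1, PDK1, EGLN3, KDM3A, PPFIA4 and FUT11 had been seen. The 24 listed genes whose values had not been seen were lower with medians aligned (median -0.15, 8 lower and 0 higher, camera p = 0.0266 with an estimated correlation). Against sgAAVS1 the same 24 genes had a median of 0.008 with sg1-IRF2 (camera p = 0.949 with an estimated correlation) and 0.14 with sg2-IRF2 (8 higher, camera p = 0.0355 with an estimated correlation). Against untransduced cells the median was -0.07 with sg1-IRF2 (5 lower, camera p = 0.150 with an estimated correlation), 0.07 with sg2-IRF2 (camera p = 0.146 with an estimated correlation) and -0.09 with sgAAVS1 (4 lower, camera p = 0.135 with an estimated correlation). Lower levels in the sg1-IRF2 libraries and higher levels in the sg2-IRF2 libraries cannot be told apart, because the control groups place the difference differently, and a difference in culture between the groups was not tested.

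Genes higher with the IRF2 guides than with sgAAVS1 had a median of -0.01 (-0.012) against untransduced cells, and 9.72% of them were called higher than untransduced cells. Most of them were thus not called higher than in untransduced cells. This cannot decide on loss of IRF2 as the cause. The genes were picked by their low values in the sgAAVS1 libraries, and untransduced cells also differ by the lack of transduction. No gene among them (0%) held at least 0.5 reads per exonic base, so none of them is a dense gene by that bound. Only 71 of the 14665 tested genes reach the bound, so a share near 0% is likely for any such set. The test therefore cannot decide on read density more widely. A difference of the sgAAVS1 libraries from the other groups is a candidate explanation. Of the 72 genes 54 were called lower in sgAAVS1 than in untransduced cells, but that comparison uses the same sgAAVS1 libraries. Whether the guide, the cells or the culture made that difference was not tested.

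At genes with at least 0.5 reads per exonic base, 71 in all, reads rose less with library size than at other genes. Within groups the median slope of log2 reads on log2 library factor was 0.433, against 1.14 over 5830 other genes of the same read counts. Without the sgAAVS1 pair the slopes were 0.502 and 1.27. Removal of duplicate reads before counting cannot be told apart from other causes, since the slope lay below the bound of 0.5 set for it only with that pair, and no biological explanation was tested. Reads drawn independently without a ceiling would give a mean chi-square near 1 between replicates. At 0.2 to 0.4 reads per exonic base it was 0.421 for sg2-IRF2, 0.656 for untransduced cells, 0.790 for sg1-IRF2 and 3.20 for sgAAVS1, and at 0.4 and above it was 0.564, 1.34, 1.76 and 9.51 in the same order. The values under 1 argue against such drawing in those pairs, while values above 1, which any further difference between replicates also gives, decide nothing.

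Zinc finger genes on chromosome 19 were over-represented among the lower genes: 21 of 216 tested were called lower (9.72%), against 0.969% of the other tested genes (Fisher's exact test, two-sided p = 2.3e-14). The set was chosen after such genes had been seen among the lower genes. The test also takes these similar genes of 1 chromosome as independent, so its p-value only describes the excess. Another 4 of the 216 were called higher, named after their values were seen: ZNF136 (0.43), ZNF30 (0.68), ZNF850 (0.26) and ZNF584 (0.67). Of the 21, 9 were also lower than in untransduced cells: ZNF304, ZNF749, ZNF772, ZNF134, ZNF211, ZNF551, ZNF814, ZNF614 and ZNF350, named after their values were seen. With sg1-IRF2 6 of the 216 genes were lower, among 73 lower genes in all, and the median of the 216 was -0.040. With sg2-IRF2 71 were lower, among 1042 in all, and the median was -0.21. In the main comparison 10 were lower with library medians aligned. Over all 216 genes the median was -0.13 against sgAAVS1, -0.11 against untransduced cells and 0.016 in sgAAVS1 against untransduced cells. What lowers these genes was not tested. Zinc finger genes are similar in sequence, so their reads are not assigned with certainty.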
